A study of Mus musculus with 20 samples.

How the data were processed

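Libraries were made from genomic DNA of colonic stem and differentiated cells with the xGen Methyl-Seq kit, and bisulfite treatment used the EZ DNA Methylation-Direct kit, per the labels' protocols. Alignment used BSMAP 2.90 and the mm10 build, per the submitters' processing notes. Read trimming, coverage filters, the region caller and its test are not given in the sources used here, and neither is how stem and differentiated cells were separated. The deposited values are methylation fractions (0 to 1) per region and sample, per the file headers. Each region also carries a deposited methylation difference, a CpG number (10 to 49) and a p-value from the authors, whose test and adjustment are not given in the sources used here. All deposited p-values lay between 4.08e-14 and 0.000999. All regions had at least 10 CpGs and an absolute difference of at least 0.1, which may be the limits used to make the table. End minus start ran from 47 to 3428 bp with a median of 525. Of 23900 fractions 18 were exactly 0. Limits of this kind remove regions with few CpGs and small differences, so the shares below describe the listed regions and not the genome. Whether coordinates count from 0 or 1 is not stated, and they are printed as deposited.

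Group, age and sex of each sample came from its labels. Identifier styles were read from the sample titles: Co for the Co ending, and otherwise GFp or LD for the beginning. The identifiers of the SPF samples at 15 weeks, of the Co style, also begin with LD, as those at 3 weeks do. What the styles stand for is not given in the sources used here. Replicates were compared before averaging: the 18 within-group pairs differed by a mean of 0.0537 to 0.0942 per region and shared at most 3 identical values, so none was counted as a duplicate. Each group holds equal numbers of male and female samples by the labels, odd replicate numbers being male and even ones female, so samples of different sex in a group come from different animals. Whether samples of 1 sex in the groups of 4, or stem and differentiated samples, come from different animals is not stated. P-values measure the spread between these samples, which includes any sex difference. Sequencing depth is unknown because no counts come with the fractions.

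Limma 3.58.1 (R 4.3.3) was fitted to the fractions of all 20 samples in 8 groups, so that groups of 2 borrow the spread of the others, with Benjamini-Hochberg adjustment over the 1195 regions of each contrast and a threshold of 0.05. Contrasts compared SPF with GF, 15 with 3 weeks, differentiated with stem cells, and the differences between those changes, the age by microbiota contrast being coded as SPF change minus GF change. Sample means over regions were compared with exact two-sided permutation tests over 12 comparisons. The limma script was tested on simulated data built from the samples' spread. In the simulation of SPF minus GF in differentiated cells at 15 weeks it called 22% of regions changed by 0.1, 78% of those changed by 0.2 and 98% of those changed by 0.3, and 9 of 995 unchanged regions. For the age by microbiota contrast in differentiated cells it called 16% at 0.2 and 80% at 0.3, and 3 of 995 unchanged regions. In each simulation 995 of the 1195 regions were unchanged, whereas 964 were called in the real SPF minus GF contrast of differentiated cells at 15 weeks. The adjusted threshold depends on how many regions change, so these shares do not carry over to contrasts with many more or fewer calls. No contrast between 3-week samples was simulated.

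Designs, alternatives, the rule for named genes and the 21 gene lists were fixed before the data were examined. The table turned out to hold 1 set of regions with 1 direction, so the planned overlap of sets was not run and the planned Fisher's exact tests between sets were replaced: list membership was compared with 100000 seeded draws of genes matched in 20 length bins from 21631 RefSeq protein-coding genes (GRCm38.p6, the same build), whereas the design fixed beforehand had named the genes of the table as background; a Fisher's exact test within the table was added. Context was compared between regions lost with age in SPF and gained with age in GF cells. Of the 666 gene symbols, 653 matched a RefSeq symbol and 657 a symbol or synonym. The lists were intestinal stem cell markers, Wnt signalling, Notch signalling and secretory fate, goblet cell and mucus, enteroendocrine cell, tuft cell, absorptive colonocyte, protein glycosylation enzymes, microbial sensing and NF-kB, epithelial immune effectors and antigen presentation, interferon response, DNA methylation machinery, imprinted genes, BMP, TGF-beta and Hedgehog signalling, lipid and bile acid metabolism with nuclear receptors, circadian clock, immune cell markers, stromal and endothelial markers, fetal and regenerative epithelium with Hippo, and tight junction, adhesion and barrier. Il33 is on 2 of them. The result of the remaining list is not reported here.

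Named genes are the 10 with the largest absolute deposited difference, each gene once, up to 4 per list by that difference, and the 5 genes with the most regions, ties going to the larger difference. Alternatives were the logit of the fraction (0 and 1 moved by 0.01), a replicate block, only the groups compared, leaving out each sample, stricter deposited limits, medians and CpG weights over regions, the nearest reference gene and promoter (within 1000 bp) or gene-body regions only. Added after seeing the data were a random block for the 6 pairs of stem and differentiated libraries that share an identifier, the 15-week GF libraries of each of 2 identifier styles alone, Fisher's exact test without length matching, genes within 100 kb counted once, context classes from differentiated cells, and regions picked and measured on GF libraries that share no identifier. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.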

Results

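DNA methylation was measured by whole-genome bisulfite sequencing in colonic stem cells and colonic differentiated cells of C57BL/6J mice that carry the Lgr5EGFP-IRES-CreERT2 allele, a knock-in that marks Lgr5-expressing stem cells with green fluorescent protein. The mice were SPF (read here as specific-pathogen-free, with a microbiota) or GF (read here as germ-free) and were 3 or 15 weeks old. The 20 samples fall into 8 groups. GF stem and GF differentiated cells at 15 weeks have 4 samples each, and each of the other groups has 2. The deposited table holds a methylation fraction, the share of methylated cytosines from 0 to 1, for each sample in 1195 regions with coordinates on the mouse mm10 build. The number of reads behind each fraction is unknown, so no interval for a single fraction is given.

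The series title places the question in how a gut microbiome that forms around weaning acts on the epigenetics of intestinal stem cells. Every region of the authors' deposited table has a negative methylation difference, with a median of -0.213 and a range from -0.555 to -0.1. Regions with a positive difference number 0 of 1195 (95% Wilson upper bound 0.320%, with regions taken as independent), although the table may have been limited to a single direction. The header does not name the groups behind that difference. Across regions it followed SPF minus GF stem cells at 15 weeks most closely (r = 0.888 across regions, which are not independent replicates). Stem cells at 15 weeks are therefore treated below as the samples on which the regions were chosen, and differentiated cells and 3-week samples as those on which they were not, although 2 of the 4 GF differentiated samples at 15 weeks share an identifier with a stem cell sample.

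In stem cells at 15 weeks, mean methylation over the regions was 0.354 ± 0.00839 (SD, n = 2) in SPF mice and 0.596 ± 0.0115 (SD, n = 4) in GF mice. The region inside Ciita, which encodes the master activator of MHC class II transcription (chromosome 16, 10490450 to 10491033, proximal enhancer-like element), stood at 0.176 ± 0.019 in SPF and 0.832 ± 0.037 in GF stem cells. Regions near H2-Aa, an MHC class II chain, and inside Cd74, the class II invariant chain, stood at 0.249 ± 0.039 against 0.760 ± 0.033 and at 0.479 ± 0.023 against 0.903 ± 0.010. Interferon-linked genes lay as far apart, with Irf1 at 0.204 ± 0.0042 against 0.773 ± 0.062 and the interferon-inducible GTPase genes Ifi47 (in a region it shares with Olfr56) and Irgm2 at 0.0404 ± 0.015 against 0.596 ± 0.090 and 0.228 ± 0.013 against 0.716 ± 0.026. Other large differences were at Hsd17b4, a peroxisomal fatty acid oxidation enzyme (0.3 ± 0.0049 against 0.904 ± 0.019), Mybpc1 (0.250 ± 0.022 against 0.838 ± 0.037), Plcb4 (0.134 ± 0.043 against 0.712 ± 0.093), Eml2 (0.223 ± 0.0023 against 0.787 ± 0.070), Lnx2 (0.187 ± 0.012 against 0.705 ± 0.039) and Tnip1, an inhibitor of NF-kB signalling (0.209 ± 0.018 against 0.729 ± 0.051). All SDs in this paragraph are over 2 SPF and 4 GF samples. By limma 1162 of 1195 regions were lower in SPF and 0 were higher, with 0 higher also at an unadjusted p under 0.05. The regions were chosen for this difference, so the count is not independent evidence of its direction.

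**Figure D1:**
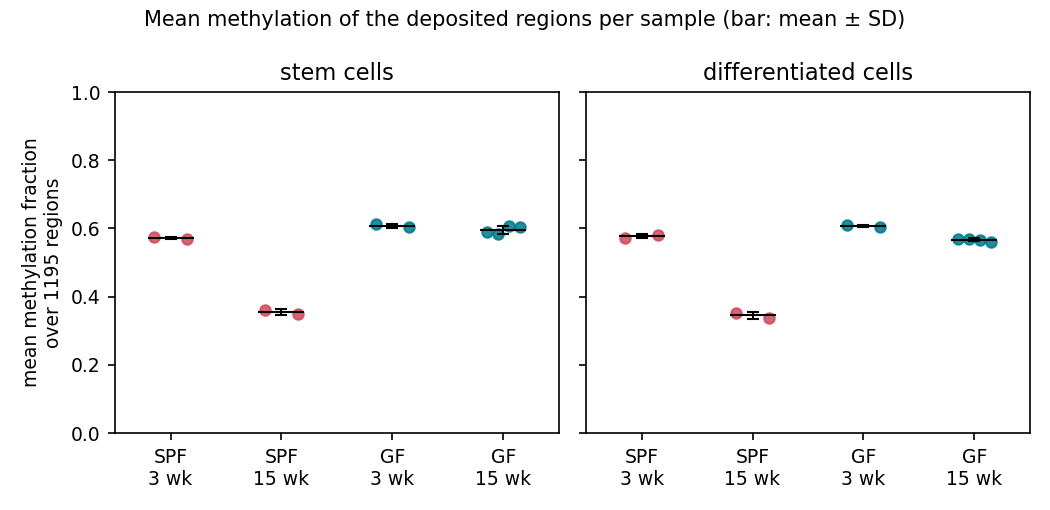
Mean methylation fraction over the 1195 regions (vertical axis, 0 to 1) in each sample, by group, for stem cells (left) and differentiated cells (right). Points are samples and bars are the group mean ± SD; the SPF samples at 15 weeks lie between 0.338 and 0.360 and all others between 0.560 and 0.612.

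Differentiated cells at 15 weeks were also lower in SPF than in GF mice at most of these regions. Mean methylation was 0.345 ± 0.0106 (SD, n = 2) in SPF and 0.567 ± 0.00456 (SD, n = 4) in GF differentiated cells, and 1167 of 1195 regions had a lower SPF mean. Ciita was lower in SPF differentiated cells by -0.677 ± 0.035 (SE, adjusted p = 5e-11), Hsd17b4 by -0.646 ± 0.038 (adjusted p = 2.5e-10), Ifi47 by -0.598 ± 0.058 (adjusted p = 6.9e-08), Eml2 by -0.581 ± 0.040 (adjusted p = 1.2e-09), H2-Aa by -0.576 ± 0.048 (adjusted p = 1.2e-08), Plcb4 by -0.572 ± 0.069 (adjusted p = 9.9e-07) and Irf1 by -0.571 ± 0.039 (adjusted p = 1.2e-09). Of the genes with the most regions, Pla2g5 (4 regions) was lower by -0.559 ± 0.041, Frmd4b (5) by -0.469 ± 0.051, Aopep (8) by -0.382 ± 0.042, Eps8 (5) by -0.323 ± 0.037 and Gm20388 (11) by -0.247 ± 0.039. Each value is for the gene's region with the largest deposited difference, which for Gm20388 is shared with Irf8. By limma 964 regions were lower in SPF and 0 higher (977 and 0 at an unadjusted p under 0.05). Against only the 15-week GF samples of each of the 2 identifier styles, Co and GFp, 947 and 894 were lower and 0 and 3 higher, and without either SPF differentiated sample at 15 weeks 1 was higher. The exact permutation test of the 2 SPF against 4 GF sample means gave p = 0.133 in both cell types. That is the smallest possible for these sample sizes with the smaller tail counted 2 times, as was done here.

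At 3 weeks few of the same regions were called different between SPF and GF mice. Ciita stood at 0.746 ± 0.017 in SPF and 0.787 ± 0.020 in GF stem cells (SD, n = 2 each), H2-Aa at 0.753 ± 0.110 and 0.723 ± 0.037, Irf1 at 0.836 ± 0.0068 and 0.880 ± 0.041 and Hsd17b4 at 0.912 ± 0.0041 and 0.862 ± 0.020. Mean methylation was 0.572 ± 0.00375 in SPF and 0.607 ± 0.00629 in GF stem cells, and 0.578 ± 0.0062 and 0.608 ± 0.00396 in differentiated cells. Limma called 0 regions in stem cells (124 at an unadjusted p under 0.05, of which 112 were lower in SPF) and 1 in differentiated cells (104 at an unadjusted p under 0.05). That region lies in Tmsb10 (chromosome 6, 72957416 to 72957523, chosen after its values were seen) and was lower in SPF by -0.508 ± 0.080 (SE, adjusted p = 0.00442). It was not called on the logit scale, and limma called 0 regions without replicate 2 and 2 without replicate 1 of the SPF differentiated cells. The exact permutation p for 2 against 2 sample means was 0.33, the smallest possible.

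Between 3 and 15 weeks SPF cells lost methylation at most of the regions. The identifiers of all SPF samples begin with LD, and the Co ending is on all of those at 15 weeks and none at 3 weeks, so age and that ending coincide in this comparison. Ciita fell from 0.746 ± 0.017 to 0.176 ± 0.019 in SPF stem cells and from 0.768 ± 0.011 to 0.104 ± 0.024 in SPF differentiated cells (SD, n = 2 each; adjusted p = 3.6e-09 and 8.1e-10). Cdca7, a gene on the stem cell list, fell from 0.567 ± 0.053 to 0.0431 ± 0.0044 and from 0.586 ± 0.045 to 0.0529 ± 0.0043. Igf2bp2 fell from 0.674 ± 0.044 to 0.104 ± 0.0011 in stem cells, and Axin2, a Wnt target, from 0.864 ± 0.0057 to 0.397 ± 0.012. Limma called 831 regions lower and 12 higher at 15 weeks in SPF stem cells and 863 lower and 11 higher in SPF differentiated cells. Of these, 773 were lower in both cell types, against 600 for independent lists of those sizes. The lists are not independent, since the 3-week stem and differentiated samples share both identifiers. The regions are also taken to have been chosen for low values in the SPF stem samples at 15 weeks, which favours a loss with age there. The counts and p-values of the SPF stem cells are not independent of that choice. The 12 regions that rose in stem cells came to 7 without replicate 1 at 15 weeks and 5 without replicate 2 at 3 weeks. In differentiated cells the 11 came to 7 without replicate 2 at 15 weeks, 6 without replicate 1 at 3 weeks and 7 without replicate 2 at 3 weeks. Fitted to the compared groups alone, they came to 20 and 18.

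GF cells changed in both directions over the same interval. Cdca7 fell from 0.523 ± 0.016 (SD, n = 2) to 0.192 ± 0.026 (SD, n = 4) in GF stem cells (adjusted p = 6.3e-06), and Smad1, a transcription factor of BMP signalling, from 0.463 ± 0.130 to 0.245 ± 0.050 (adjusted p = 0.0032). Prdm1, which encodes the repressor Blimp1, rose from 0.572 ± 0.023 to 0.778 ± 0.021 (adjusted p = 0.0018), and Galnt10, a GalNAc transferase of mucin-type glycosylation, from 0.233 ± 0.018 to 0.463 ± 0.054 (adjusted p = 0.0018). In GF differentiated cells Prdm1 rose from 0.577 ± 0.014 to 0.821 ± 0.031 and Galnt10 from 0.215 ± 0.082 to 0.484 ± 0.065. Limma called 161 regions lower and 103 higher with age in GF stem cells, and 215 lower and 80 higher in GF differentiated cells. Both cell types shared 115 of the lower regions (29.0 for independent lists) and 56 of the higher regions (6.9 for independent lists). These lists are not independent either, since the GF cell types share both identifiers at 3 weeks and 2 of 4 at 15 weeks. The regions are also taken to have been chosen for high values in the GF stem samples at 15 weeks, which favours gains over losses there. The counts and p-values of the GF stem cells are not independent of that choice. Without replicate 1 or replicate 2 of the 3-week GF stem cells the counts in stem cells were 89 and 97 lower and 66 and 59 higher, and without replicate 1 of the 3-week GF differentiated cells they were 127 and 44 in differentiated cells. Fitted to the GF stem cell groups alone, 90 were lower and 58 higher.

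The change with age differed between SPF and GF mice in both cell types. For Ciita the SPF change minus the GF change was -0.615 ± 0.054 in stem cells and -0.714 ± 0.054 in differentiated cells (SE, limma, adjusted p = 3.7e-07 and 4.2e-08). The corresponding differences were -0.654 ± 0.058 and -0.595 ± 0.058 at Hsd17b4, -0.648 ± 0.061 and -0.468 ± 0.061 at Eml2, -0.542 ± 0.074 and -0.583 ± 0.074 at H2-Aa, -0.525 ± 0.060 and -0.528 ± 0.060 at Irf1, and -0.401 ± 0.053 and -0.514 ± 0.053 at Cd74. At Prdm1 and Galnt10, where GF cells gained methylation, they were -0.189 ± 0.064 and -0.370 ± 0.064, and -0.200 ± 0.071 and -0.320 ± 0.071. At Cdca7, lost in both SPF and GF mice, they were -0.194 ± 0.055 and -0.191 ± 0.055 (adjusted p = 0.0094 and 0.0091). The mean over regions was -0.206 in stem cells and -0.192 in differentiated cells. Limma called 651 regions with a more negative change in SPF stem cells and 0 with a less negative one (0 at an unadjusted p under 0.05), and 567 and 1 in differentiated cells. The 2 lists shared 416 regions, against 309 for independent lists, although samples of the 2 cell types partly share identifiers. Without replicate 2 of the 15-week SPF stem cells the stem cell count was 410, and without replicate 4 of the 15-week GF stem cells 2 had a less negative change. In differentiated cells the 1 region, at Tmsb10, became 2 without replicate 1 or 4 of the GF cells at 15 weeks or replicate 2 at 3 weeks, and 0 on the logit scale. With only the 15-week GF samples of the Co or the GFp identifier style, the mean was -0.196 or -0.216 in stem cells and -0.195 or -0.189 in differentiated cells. The 15-week stem libraries that enter this contrast are those on which the regions were chosen; the differentiated libraries are not.

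**Figure D2:**
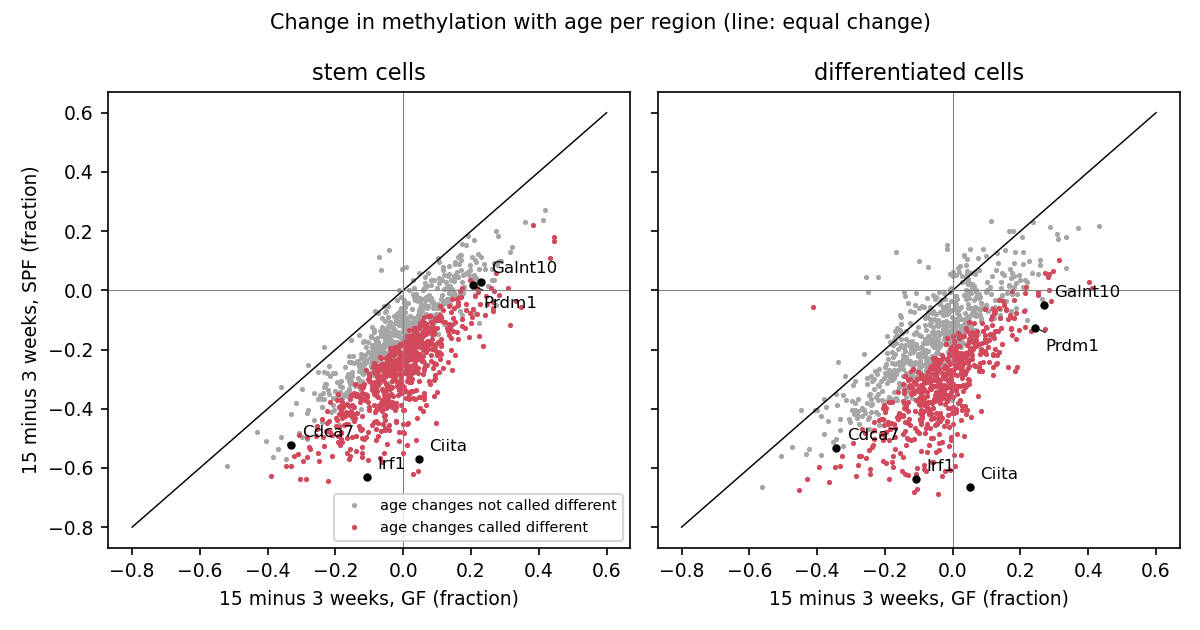
Change in methylation fraction from 3 to 15 weeks per region in GF mice (horizontal axis) against SPF mice (vertical axis) for stem cells (left) and differentiated cells (right); the line marks equal change. Red points are the 651 and 568 regions whose changes limma called different at an adjusted p under 0.05, nearly all below the line, with Ciita, Irf1, Cdca7, Prdm1 and Galnt10 marked.

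**Figure D3:**
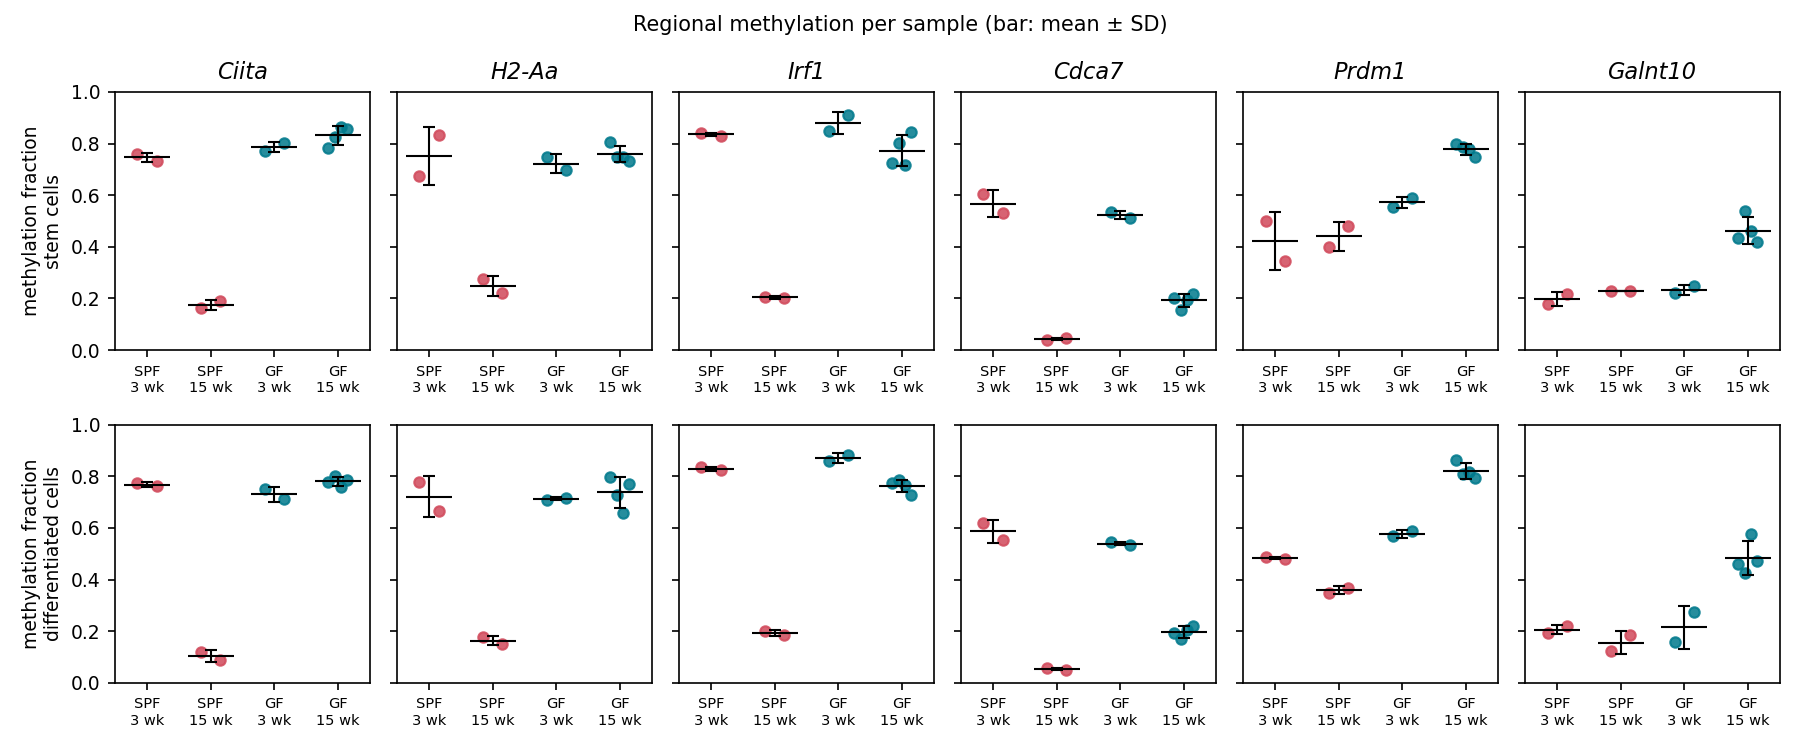
Methylation fraction (vertical axis, 0 to 1) per sample at regions of 6 genes in stem cells (top) and differentiated cells (bottom), by group; points are samples and bars the group mean ± SD. Ciita, H2-Aa and Irf1 are low in the SPF samples at 15 weeks, Cdca7 is lower at 15 weeks in SPF and GF mice, and Prdm1 and Galnt10 are highest in GF mice at 15 weeks.

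Differentiated and stem cells of mice of the same age and status were called different at few of the regions. In SPF mice limma called 0 regions at 3 weeks (63 at an unadjusted p under 0.05) and 0 at 15 weeks (131). In GF mice at 3 weeks it called 2 regions higher in differentiated cells, in Tmsb10 (by 0.449 ± 0.080) and Bend7 (by 0.260 ± 0.051), both chosen after their values were seen, and neither was called on the logit scale. Leaving out replicate 1 or 2 of the stem cells gave 0 and 1 regions, and replicate 1 or 2 of the differentiated cells 1 and 0, with 1 region lower in each of the last pair. In GF mice at 15 weeks 83 regions were lower and 14 higher in differentiated cells. The sample means averaged 0.567 and 0.596, with all 4 differentiated samples below all 4 stem samples (exact two-sided permutation p = 0.0286, the smallest possible, and 0.343 after adjustment over 12 comparisons of sample means). The regions are taken to have been chosen for high values in these GF stem samples, which favours lower values in differentiated cells. Neither the counts nor this p-value are independent of that choice. Without replicate 1, 2 or 3 of the differentiated cells 41, 54 and 41 regions were lower and 4, 9 and 2 higher, and without replicate 1 or 4 of the stem cells 52 and 54 were lower, with 6 higher without replicate 4. On the logit scale 49 were lower and 6 higher, in a fit of these groups alone 23 and 0, and within the Co and GFp identifier styles 17 and 3, and 30 and 5. The SPF minus GF difference at 15 weeks was called different between differentiated and stem cells at 0 regions (66 at an unadjusted p under 0.05).

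Genes of antigen presentation and epithelial immune effectors held 18 of the regions at 14 genes. All 18 were lower in SPF differentiated cells at 15 weeks, with a median difference of -0.358, and 15 had a more negative age change in SPF mice in each cell type (16 in differentiated cells adjusted over the list alone). Over all 1195 regions 80.7% were called lower in this comparison, with a median of -0.213. A more negative age change in SPF mice was called at 54.5% of all regions in stem and 47.4% in differentiated cells. Besides Ciita, H2-Aa and Cd74, Duoxa2, needed to bring the oxidase Duox2 to the cell surface, was lower by -0.471 ± 0.044. The interferon response list held 11 regions at 8 genes, all lower in SPF differentiated cells with a median of -0.252. Of these 10 differed in their age change in stem cells and 9 in differentiated cells (10 adjusted over the list alone). Irgm2 was lower by -0.472 ± 0.043, Ifnlr1, a subunit of the interferon lambda receptor, by -0.277 ± 0.043, and the region shared by Rnf31 and Irf9 by -0.215 ± 0.059. On the microbial sensing and NF-kB list 4 of 5 regions were lower (5 adjusted over the list alone). They included Tnip1 (-0.524 ± 0.044), Nlrc5, an activator of MHC class I genes (-0.306 ± 0.046), the kinase gene Tbk1 (-0.285 ± 0.043) and the RNA sensor gene Ifih1 (-0.243 ± 0.051). The errors are SEs from limma over 2 SPF and 4 GF samples.

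Among the lists of epithelial identity, all 5 regions at intestinal stem cell marker genes were lower in SPF differentiated cells at 15 weeks, by -0.332 ± 0.065 at Prom1, -0.254 ± 0.049 at Axin2, -0.188 ± 0.047 at Cd44 and -0.144 ± 0.036 at Cdca7, and 3 differed in age change in each cell type. With 80.7% of all regions called lower in this comparison, counts over so few regions set no list of this paragraph apart. The same holds for the age change, more negative in SPF at 54.5% of all regions in stem and 47.4% in differentiated cells. The 4 goblet cell and mucus regions were all lower too, by -0.350 ± 0.063 at Muc13, -0.244 ± 0.062 at Muc1 and -0.224 ± 0.053 at Sytl2. Each of the 5 regions on the fetal and regenerative epithelium and Hippo list was lower (Tead1 -0.354 ± 0.046, Igf2bp2 -0.309 ± 0.046, Il33 -0.220 ± 0.043, Ly6e -0.160 ± 0.055), as were all 3 of the tight junction, adhesion and barrier list (Itga6 -0.356 ± 0.045, Pard3 -0.190 ± 0.049, Cldn14 -0.153 ± 0.040). The 1 absorptive colonocyte region, at Ceacam1, was lower by -0.216 ± 0.050, and the 1 Notch and secretory fate region, at Jag1, by -0.160 ± 0.061. Of 4 Wnt signalling regions 2 were lower, Wnt3a by -0.198 ± 0.049 and Lrp5 by -0.129 ± 0.052, while Tcf7l2 stood at 0.0701 ± 0.032 and 0.0771 ± 0.022. Of 6 glycosylation enzyme regions 3 were lower, among them Galnt10 (-0.329 ± 0.047) and St3gal3 (-0.315 ± 0.049), while Galnt7 and Galnt17 differed by 0.00791 ± 0.080 and -0.00777 ± 0.074. Of 4 regions on the lipid, bile acid and nuclear receptor list 2 were lower, Cpt1a (-0.246 ± 0.049) and Nr3c2 (-0.235 ± 0.055), and Pparg was not called (-0.0599 ± 0.047). The 1 BMP, TGF-beta and Hedgehog region, at Smad1, was not called (-0.0464 ± 0.048). The enteroendocrine, tuft cell, DNA methylation machinery and circadian clock lists, as fixed beforehand, held 0 regions. The 0 for DNA methylation machinery covers the genes on that list alone, and Cdca7 was counted on the stem cell list only.

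Of markers of other cell types, the immune cell list had 1 gene with a region against 1.57 expected from genes of like length. The stromal and endothelial list had 3 against 1.13 (length-matched random draws, adjusted p = 0.528). Whether these genes are also expressed in epithelial cells was not tested. The immune region, at Prdm1, was lower in SPF differentiated cells by -0.463 ± 0.042 (SE). The 3 stromal and endothelial regions were at Vwf (-0.375 ± 0.058), Pecam1 (-0.291 ± 0.053) and Acta2 (-0.165 ± 0.055). All 3 were lower too, as were 80.7% of all regions. Imprinted genes, expressed from a single parental allele, held 10 regions. In SPF stem cells 5 of them were lower than in GF stem cells at 15 weeks (1 adjusted over the list alone), and in differentiated cells 0 were by limma. Against only the GF samples of the Co identifier style 1 was lower in stem cells (median difference -0.0894), and against only those of the GFp style 8 were (-0.332). In differentiated cells these counts were 0 (-0.0176) and 3 (-0.121). In stem cells at 15 weeks Igf2r stood at 0.285 and 0.422 in the SPF samples, 0.381 and 0.491 in the Co and 0.827 and 0.813 in the GFp samples of GF mice, and Impact at 0.461 and 0.456, 0.479 and 0.446, and 0.806 and 0.757. The difference in differentiated cells was -0.0814 ± 0.110 at Igf2r, -0.147 ± 0.120 at Inpp5f, -0.0211 ± 0.080 at Impact and 0.00344 ± 0.073 at Cdkn1c. Adjusted over the list alone, the age change also differed at 5 rather than 3 glycosylation regions and 3 rather than 2 lipid list regions in stem cells, and at 1 rather than 0 colonocyte regions and 3 rather than 2 stromal regions in differentiated cells.

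The immune and imprinted lists held more of the genes with a region than genes of like length did. Antigen presentation and immune effector genes numbered 14 of 76 against 1.28 expected (adjusted p = 0.00042), interferon response genes 8 of 58 against 1.39 (adjusted p = 0.00112) and imprinted genes 10 of 43 against 1.86 (adjusted p = 0.00042), by length-matched random draws with Benjamini-Hochberg adjustment over 21 lists. The stem cell list had 4 of 27 against 1.22 (adjusted p = 0.31), the goblet list 3 of 30 against 0.743 (0.31) and the microbial sensing list 5 of 75 against 2.12 (0.412). No other list had an adjusted p under 0.528. With each region given to its nearest reference gene 6 lists passed, the stem cell (adjusted p = 0.0182), microbial sensing (0.0435) and stromal (0.047) lists being added. The imprinted list then held 8 of 43 against 2.68 (0.0385). With genes within 100 kb counted once, the same draws gave 11 of 53 antigen presentation genes against 0.976 (adjusted p = 0.00042). Interferon genes numbered 7 of 43 against 1.1 (0.00098) and imprinted genes 8 of 32 against 1.53 (0.00098). Fisher's exact test without length matching, chosen after the data were seen, passed 4 lists, the stem cell list being added (adjusted p = 0.0441). Among regions with an absolute deposited difference of at least 0.3 the authors' deposited table held 0 imprinted, stem cell or stromal genes, where 0.289, 0.19 and 0.167 were expected. Within the table, genes with a region lost with age in SPF and not called in GF differentiated cells numbered 370 of 666. They made up 12 of the 14 antigen presentation genes (Fisher's exact test, adjusted p = 0.288), 7 of the 8 interferon genes (0.458) and 0 of the 10 imprinted genes (0.0058). Which genes had enough covered CpG sites to enter the table is unknown, so the protein-coding background, chosen after the table was seen, includes genes that could not have been called.

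**Figure D4:**
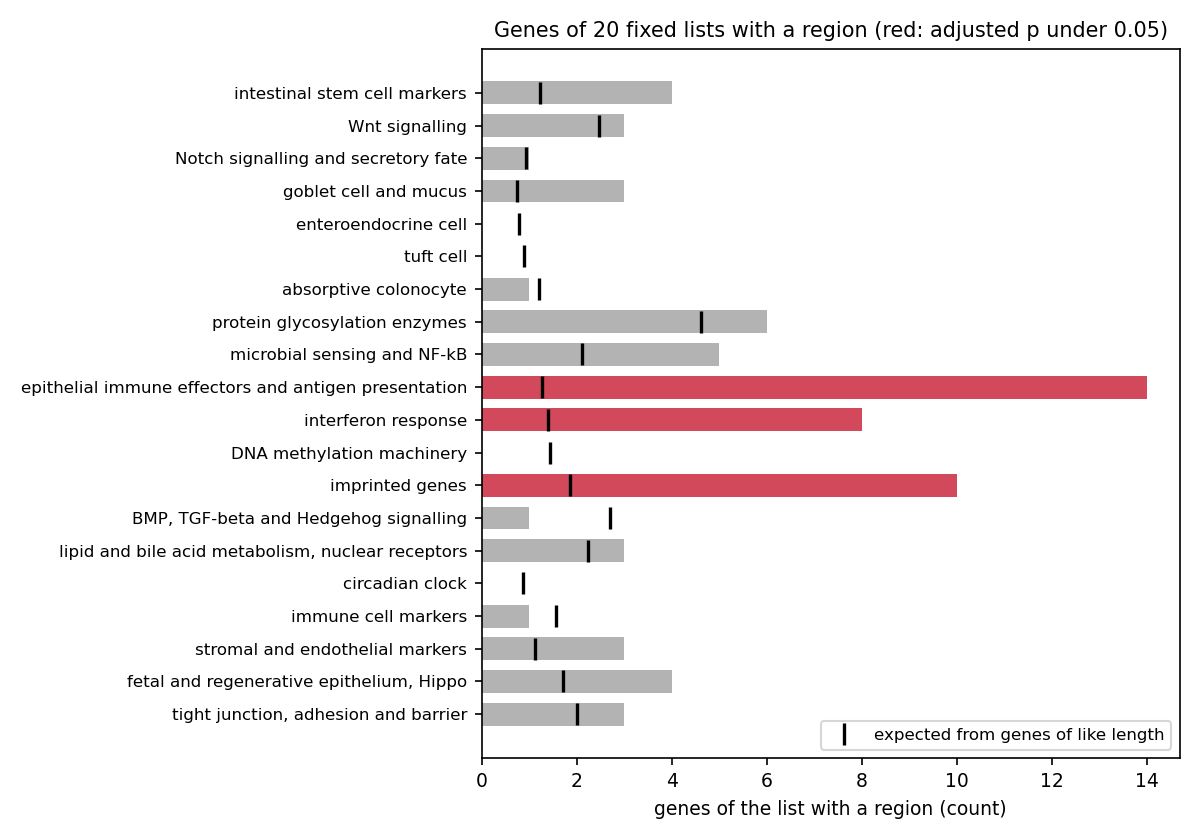
Number of genes of each of 20 gene lists that have a region in the deposited table (bars, horizontal axis) and the number expected from genes of like length (black marks). Red bars are the 3 lists with an adjusted p under 0.05, with 14, 8 and 10 genes against 1.28, 1.39 and 1.86 expected.

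By the deposited annotation 720 regions (60.3%) lay within a gene body, 46 (3.85%) near a transcription start, and 440 (36.8%) in neither. Candidate cis-regulatory elements covered 588 regions (49.2%), of which 421 were distal enhancer-like, 116 proximal enhancer-like and 24 promoter-like, the last including the regions at Ifi47, Igf2r, Cdkn1c, Inpp5f and Ly6e. Regions lost in SPF stem cells lay in such elements in 407 of 825 cases and regions gained in GF stem cells in 54 of 97, leaving out the 6 that were both (Fisher's exact test, odds ratio 0.775, p = 0.283). By the same exact test, the gene body shares were 59.5% and 67.0% (odds ratio 0.724, p = 0.188) and for promoter-like elements 1.33% and 3.09% (odds ratio 0.423, p = 0.175). Among regions with an absolute difference of at least 0.3 the odds ratios turned to 1.6 for these elements and 2.3 for gene bodies (Fisher's exact test, p = 0.676 and 0.391). Only 5 gained regions entered that comparison, with 0 in promoter-like elements. Exons and introns were not told apart here.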

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

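The tests of technical explanations here, and the bounds they were read against, were chosen after the results were seen, and the count of immune marker genes replaced a first test, the share of the level lost, once its value was known.

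The change with age differed between SPF and GF mice at 651 regions in stem cells and 568 in differentiated cells by limma's interaction contrast. Lower values in all libraries with the Co ending, as a cause of the loss in SPF mice, are argued against by the 15-week GF libraries: over the regions lost in SPF, those with that ending differed from those of the GFp style by a median of -0.00956 in stem cells (0.0135 in differentiated cells), against a loss of -0.273. The Co ending is on all SPF libraries at 15 weeks and none at 3 weeks, so within SPF mice it coincides with age. Choice of regions for low values in the SPF stem libraries is argued against by the differentiated libraries, where the median age change over all regions was -0.233 (at 15 weeks these share no identifier with the stem libraries, at 3 weeks they share both). Immune cells in the 15-week SPF samples cannot be told apart from a change in epithelial cells. Immune cell marker genes held regions at 0.637 times the number expected, but that was 1 gene, Prdm1. With age in SPF mice its region changed by 0.0169 ± 0.048 (SE) in stem cells, which was not called. In SPF differentiated cells it changed by -0.126 ± 0.048 (limma, adjusted p = 0.025). A contaminant free of methylation, as the only cause, would need to make up at least 46.4% of the stem cell sample for the median region lost, 72.4% at the 90th percentile and 94.9% for the largest loss (49.3%, 75.9% and 95.2% in differentiated cells). Stromal or endothelial cells in the 15-week SPF samples were not tested as a cause. A biological difference between SPF and GF mice stays open as untested.

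Regions gained with age in GF stem cells numbered 103, with a median gain of 0.206. In the GF differentiated libraries the median change was 0.152, but 2 of the 4 at 15 weeks and both at 3 weeks share identifiers with the stem libraries. Choice of regions for high values in the 15-week GF stem libraries is argued against by differentiated libraries that share no identifier with those on which 103 regions were picked anew, by style and 3-week replicate: the 4 medians ran from 0.109 to 0.133, with 85 or 86 of 103 positive. All 4 GF stem libraries at 15 weeks are taken to have entered the authors' own choice. Of the 15-week differentiated libraries only those of the Co style, with medians of 0.121 and 0.109, share no identifier with any of them. A batch of libraries with a single identifier style stays open. The 4 medians were 0.129 and 0.133 with the GFp style at both ages and 0.121 and 0.109 with the Co style at 15 weeks. Their bootstrap intervals over regions began at 0.0625 to 0.1, not above the bound of 0.1. All GF libraries at 3 weeks have the GFp style, so a batch of theirs may also contribute, and an age difference in GF mice stays open as untested.

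Differentiated cells of GF mice at 15 weeks differed from stem cells at 97 regions. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 5. The regions were chosen for high values in the GF stem libraries at 15 weeks, which favours the real split, so chance values of those libraries cannot be excluded by this count. The split by identifier style gave 4. The GF age change differed between differentiated and stem cells at 2 regions, in Tmsb10 and in the region of Dand5 and Gadd45gip1, both chosen after their values were seen, and at 0 on the logit scale and 0 to 4 when single samples were left out.

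Single samples stood apart from the other 3 of their group at 5 of 120 region and group combinations tested, about what chance gives at 1 in 20. In GF stem cells at 15 weeks these were Pecam1 (0.600 against a median of 0.707) and Pparg (0.538 against 0.673). In GF differentiated cells at 15 weeks they were Lnx2 (0.412 against 0.566), Muc13 (0.340 against 0.515) and Wnt3a (0.699 against 0.621).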

How the results depend on the processing

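Of 360 alternative values of counts, mean age changes and odds ratios, 279 stayed within 1.5 times of the value reported or on its side of the threshold. Of 2650 for named regions, lists and sample means, 2492 stayed, 95 were weaker, 54 stronger, 6 differences of sample means moved by more than the SD between replicates, with the same sign, when medians over regions replaced means, and 3 came to 0: the ratio to expected of the stem cell, imprinted and stromal lists among regions with an absolute difference of at least 0.3, where so few genes were expected (0.19, 0.289 and 0.167) that 0 shows no change of direction. The cause was not tested where values moved, except that stricter limits and left-out samples leave fewer regions or samples. Read depth, which limits each fraction, is unknown. The overlap of region sets was not run, since the table holds 1 set. Identifier styles and the shared identifier block were added after the data were seen.

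The 1195 regions became 777 with p at most a 10th of the largest deposited, 166 with a difference of at least 0.3, 50 with at least 20 CpGs and 666 with genes counted in place of regions. On the logit scale, regions lower in SPF differentiated cells at 3 weeks came to 0, differentiated against stem cells in GF mice to 0 higher at 3 weeks and 49 lower and 6 higher at 15 weeks, the less negative age change in SPF differentiated cells to 0, and the GF age change between cell types to 0. With only the groups compared, these were 0, 0, 23, 0, 3 and 0, SPF differentiated cells at 15 weeks had 1 higher, age gains in SPF cells came to 20 (stem) and 18 (differentiated), and GF stem cells had 90 lower and 58 higher. With Co identifiers only, GF differentiated against stem cells gave 17 lower and 3 higher, the less negative age change 2 (stem) and 4 (differentiated), and the GF age change between cell types 1 lower and 1 higher. With GFp identifiers only, these gave 30 and 5, 2 in differentiated cells, and 3 regions higher in SPF differentiated cells at 15 weeks. Nearest reference genes gave 6 lists.

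Leaving out each sample in turn, with a lone sample assumed to vary like the other groups, gave 0 to 1 higher in SPF differentiated cells at 15 weeks and 0 to 2 lower at 3 weeks. Age gains were 5 to 9 in SPF stem and 6 to 8 in SPF differentiated cells. GF age losses and gains were 89 to 170 and 59 to 112 in stem cells and 127 to 210 and 44 to 84 in differentiated cells. GF differentiated against stem cells gave 0 to 1 lower and 0 to 1 higher at 3 weeks and 41 to 110 and 2 to 18 at 15 weeks. The age change differed at 410 to 670 lower and 0 to 2 higher in stem cells and 1 to 2 higher in differentiated cells, and the GF age change between cell types at 0 to 4. With a random block for the 6 library pairs sharing an identifier this last count was 4.

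With the replicate number as a replicate block, SPF minus GF at 15 weeks gave 1117 lower in stem and 933 in differentiated cells, the age change 625 in stem cells and 545 lower and 4 higher in differentiated cells, and GF differentiated against stem cells 1 higher at 3 weeks. The numbers follow sex, and the 6 pairs of libraries sharing an identifier also share a number. Deviations of the 52 pairs sharing only a number had a median correlation of 0.0321, and 3 of the 6 pairs sharing an identifier were over 0.1.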

Other observations

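The tests here were chosen after the results were seen. The 1 Mb window of chromosome 17 from 34000001 to 35000000, in the MHC, held 10 regions, including those at H2-Aa, H2-Ab1, Psmb8 and Psmb9, against a mean of 1.72 over the 694 windows with a region. A window of chromosome 6 from 31000001 to 32000000 held 9, none with a gene in the table, and 3 windows held 8, and the difference between them was not tested. Psmb8, an immunoproteasome subunit gene (start 34198719), and Tnf, a cytokine gene outside that window (start 35200329), were chosen after their values were seen. They fell from 0.626 to 0.255 and from 0.810 to 0.298 in SPF differentiated cells between 3 and 15 weeks (limma, adjusted p = 1e-05 and 2.7e-08), while GF differentiated cells stood at 0.674 and 0.694 and at 0.795 and 0.765.

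Imprinted genes were over-represented among the regions, yet the SPF minus GF difference at 15 weeks had a median of -0.198 in stem cells and -0.0803 in differentiated cells, against -0.221 and -0.214 at the other regions. The difference shrank by a mean of 0.123 at the 10 imprinted regions and 0.0194 at the others (permutation p = 0.0006, two-sided, 100000 draws). The 10 regions are not 10 separate loci, since those at Peg10 and Sgce start at 4747474, 4747953 and 4748273 on chromosome 6. The draws took regions as independent, so the permutation p-values of this paragraph may be too small. Among the GF stem libraries at 15 weeks, however, the 2 with GFp identifiers stood above the 2 with Co identifiers by a mean of 0.220 at the imprinted regions and 0.0174 at the others (permutation p = 2e-05, two-sided, the smallest these draws can give), and both lay above both at 7 of 10 regions, against 24.1% of the others. The GF differentiated libraries of the same styles differed by 0.123 and -0.00693 (permutation p = 2e-05). The 3-week GF stem libraries, also of the GFp style, stood at 0.45 at Igf2r and 0.437 at Impact, near the 15-week Co values of 0.436 and 0.462. At Cdkn1c (0.469) and the Peg10 and Sgce region from 4747474 (0.657) they lay nearer the 15-week GFp values of 0.55 and 0.769. The shrinkage therefore cannot tell chance values of the stem libraries at single regions from a shared feature of the 15-week libraries with GFp identifiers, which may be technical or biological. A difference confined to stem cells stays open too, although limma called 0 of all regions for a difference between the cell types in the SPF minus GF difference.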
